A study of Mus musculus with 6 samples.

How the data were processed

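RNA of mouse GMLPs sorted from bone marrow and cultured with DOX for 3 days was sequenced, with 3 libraries from mice with MLL-ENL (ME) and 3 from mice with LIN28B and MLL-ENL (L28BME). RNA was isolated with the Norgen Single Cell RNA Purification Kit and libraries were made with the TruSeq Stranded mRNA kit. Per the submitters' processing notes, the authors used bcl2fastq, HISAT2, StringTie and DESeq2 with the GRCm38 assembly; versions, and whether strand was used in quantification, are not given in the sources used here. The deposited values are TPM, made by the authors for each gene and library. The deposited table also gives the percent GC of each gene, a property of the annotation that does not differ between libraries.

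There were 60496 entries for 55471 gene IDs, of which 431 appeared more than once, 0 of them with values on more than one entry. Of these IDs, 23940 had a TPM above 0 in some library. There were 15 symbols in date form, and genes were matched by ID. The TPM summed to between 999919 and 999996 per library, and mt-Co1 was the most abundant gene in each. Because TPM are not counts, depth is unknown, count models were not used here, and no interval is given for single values. Positions and biotypes came from GENCODE for GRCm38, which held 13336 of the 13348 tested IDs.

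Values were analysed as log2(TPM + 1) for genes with a TPM of at least 1 in at least 3 of the 6 libraries. Groups were compared with limma 3.58.1 in R 4.3.3, with an intensity trend and two-sided tests, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05. Gene lists, 30 in all, of blood cell types, let-7 and MLL-fusion targets, cell cycle, metabolism and quality were written before the data were examined, as were the main tests and the rule for named genes. Lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over 29 lists, with an estimated correlation and limma's fry as alternatives. Members of each list were also adjusted over the list alone. Some lists share members, which is stated where it matters.

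Named genes were the 12 called genes with the largest positive and the 12 with the largest negative log2 fold change among those with a mean of at least 5 TPM in the higher group, no overlap between groups and no provisional gene symbol, the design genes, and up to 4 members of each list with the smallest p. Other genes that the text names, such as further called members of lists and genes with let-7 sites, were chosen after their values were seen. Some genes that the rule selects are not reported here. Where a group was listed at 0 in every library, no fold is given. Equal replicate numbers are not stated to share an animal or day and were not treated as pairs.

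Alternatives were other pseudocounts, filters, scalings and limma options, a term for replicate number, leaving out each library, and a larger minimum change. Further ones were chosen after seeing the data: removal of a GC trend, summing of genes that share exonic bases on the same strand, protein-coding genes only, lists without shared members, and the fetal program without Lin28b. The procedure was tested on simulated data with 13348 genes of which 200 were changed: 68.7% of genes changed 1.5-fold, 89.6% changed 2-fold and 93.9% changed 4-fold were recovered, and 4% of calls were false. The changed genes were drawn only from those with an average of at least 5 TPM in ME, and the noise was independent between genes. The recovery rates therefore do not cover genes of lower abundance or changes under 1.5-fold. When only the primary granule list was lowered, camera called 2 lists. Other lists, such as MYB targets, share members with the lowered one, so the second call need not be false. Sites for let-7 were sought in annotated 3′ UTRs of protein-coding genes. Other tools were rtracklayer 1.62.0, data.table version 1.17.8, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.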

Results

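RNA sequencing compared mouse blood progenitors that carried the leukaemia fusion MLL-ENL alone (ME) with progenitors that carried it together with LIN28B (L28BME). The comparison asks how LIN28B, an RNA-binding protein of fetal blood cells that blocks the maturation of let-7 microRNAs, alters the transcriptome of cells with the fusion. The cells were granulocyte-monocyte-lymphoid progenitors (GMLPs) from bone marrow, sorted as lineage-negative cells with Kit, Sca1 and CD48 and without CD150, and were cultured with doxycycline (DOX) for 3 days. Each group had 3 libraries, and the deposited values were TPM, a transcript abundance scaled to a fixed total per library. The sequencing depth behind each value is therefore unknown and no counting interval can be given. The number of genes at a TPM of at least 1 lay between 13215 and 13288 per library. Pearson correlations of log2(TPM + 1) across genes, which are not independent replicates, were 0.987 to 0.988 within groups and 0.977 to 0.980 between groups. The first principal component, with 43.9% of the variance, separated the groups. Mitochondrially encoded RNA made up 4.12 to 4.35% of the TPM in ME libraries and 4.49 to 4.85% in L28BME libraries. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

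L28BME cells had higher levels of let-7 target genes and lower levels of genes of granulocyte-monocyte progenitors and primary granules. The list of the latter, called primary granule genes for short, also holds genes of other proteins, such as the transcription factor Gfi1. Of 16 megakaryocyte genes, 7 were higher, or 6 without any 1 library, and the call of that list was lost with an estimated correlation (camera adjusted p = 0.185). The let-7 targets Hmga2 and Arid3a rose 6.46-fold and 3.13-fold, and Pf4, which encodes a platelet chemokine, rose from 19.3 ± 1.53 to 52.4 ± 6.08 TPM (mean ± SD, n = 3 per group here and below). In the list of granulocyte-monocyte progenitor and primary granule genes, Ms4a3 fell from 682 ± 57.6 to 239 ± 3.05 TPM. Ctsg, which encodes cathepsin G, fell from 2526 ± 39.9 to 1711 ± 13.6 TPM. Of 13348 genes tested, 1105 were higher and 881 lower in L28BME, and 11362 were not called (limma on log2(TPM + 1), Benjamini-Hochberg adjusted p under 0.05). Most changes were small, with a median absolute log2 fold change of 0.39 among called genes, and 121 genes rose and 65 fell by at least 1 on the log2 scale. The values of the groups did not overlap for any of the 1986 called genes, and for 36.7% of all tested genes, where chance gives 10%. With 2 libraries in a group the counts were lower. They were 693 higher and 553 lower without ME replicate 1, 617 and 461 without ME replicate 2, and 658 and 477 without ME replicate 3. They were 638 and 534 without L28BME replicate 1, 682 and 582 without L28BME replicate 2, and 679 and 551 without L28BME replicate 3. Of 29 gene lists tested with camera, 6 were called: let-7 targets, the fetal HSC program, megakaryocyte genes, B-lymphoid genes and G2/M genes as higher, and primary granule genes as lower. With an estimated correlation between genes, the calls of let-7 targets and primary granule genes held and the other 4 were lost.

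The gene that defines the contrast was read first. Lin28b (ENSMUSG00000063804, chromosome 10, 45376620 to 45486395 on the minus strand of GRCm38) was listed at 0 in every ME library and at 11.2, 11.7 and 11.9 TPM in the L28BME libraries (limma adjusted p = 2.50e-05). These values are those of the mouse gene model. They cannot tell transcripts of the endogenous gene from those of an introduced LIN28B, and may not measure the LIN28B level. Lin28a, the paralog of Lin28b, rose from 1.29 ± 0.373 to 3.47 ± 1.31 TPM (log2 fold change 0.94, SE 0.24, adjusted p = 0.0486). That call was lost at adjusted p = 0.0539 to 0.133 without any 1 of the 6 libraries. Myb, a transcription factor of immature blood cells, fell from 363 ± 4.29 to 316 ± 2.56 TPM (log2 fold change -0.20, adjusted p = 0.00469). The mouse genes of the fusion partners did not pass the test over all genes. Kmt2a, the mouse MLL gene, was at 14.7 ± 0.522 TPM in ME and 13.8 ± 1.14 TPM in L28BME (adjusted p = 0.493). Mllt1, the mouse ENL gene, was at 49.9 ± 1.95 and 54.99 ± 1.47 TPM (adjusted p = 0.106). Mybbp1a, which encodes a MYB-binding nucleolar protein, was at 382 ± 10.1 and 379.7 ± 15.02 TPM (log2 fold change -0.01, SE 0.039, adjusted p = 0.914). As a list of 6 these genes were not called by camera (adjusted p = 0.344), with 2 higher and 1 lower over all genes and 3, with Mllt1, and 1 adjusted over the list alone.

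**Figure D1:**
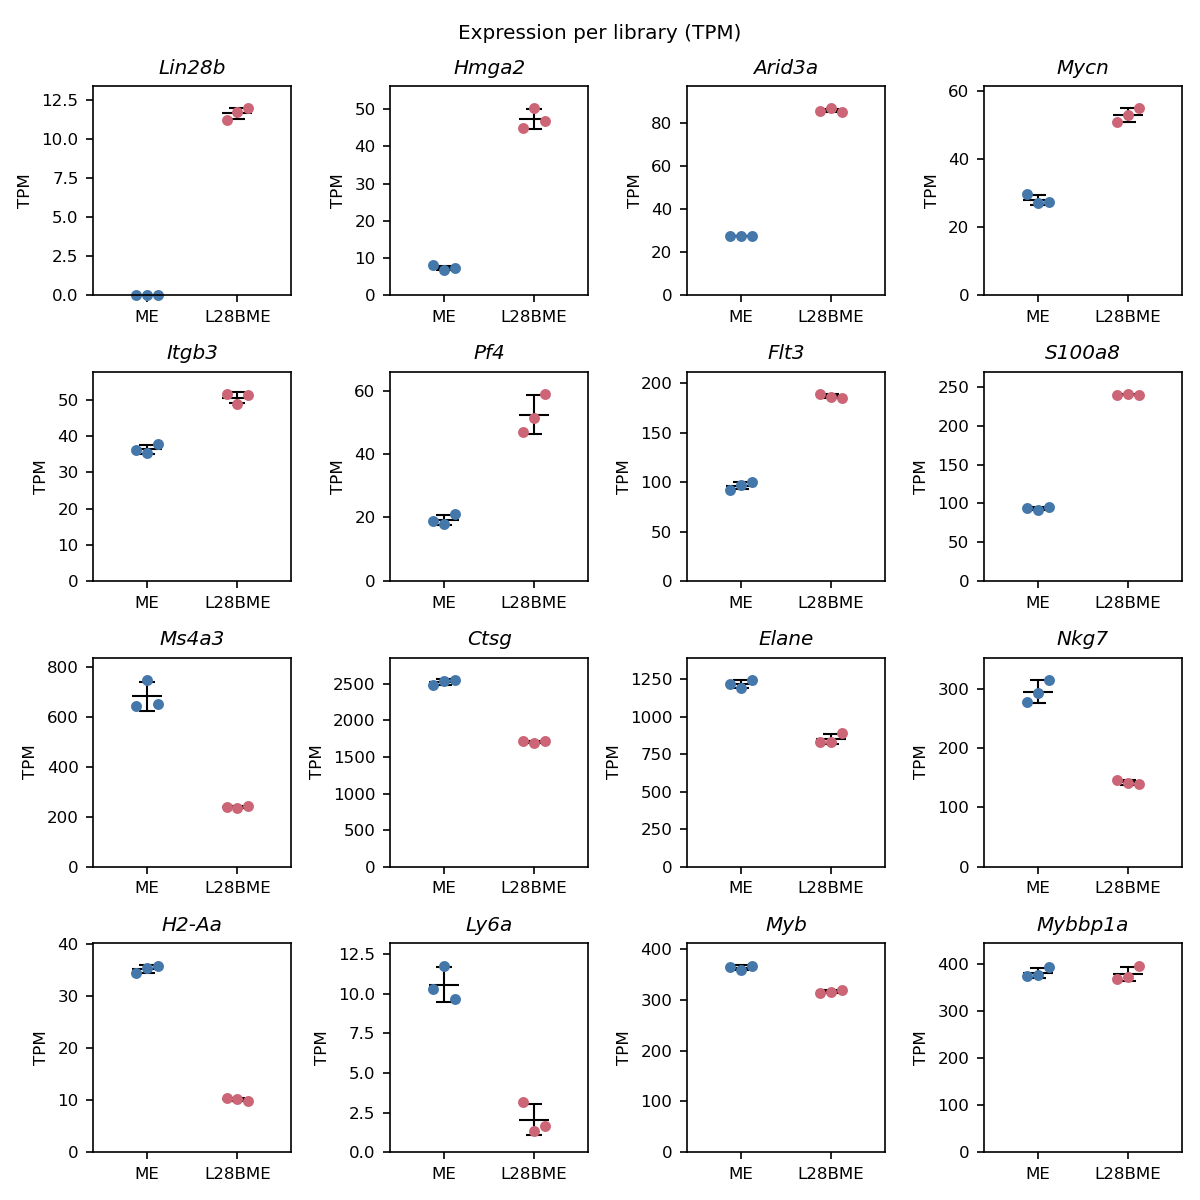
TPM of 16 genes in each of the 6 libraries, with ME in blue and L28BME in red; black bars give the mean and SD of the 3 libraries of a group, except for Lin28b in ME, which was listed at 0 in all of them. Lin28b, Hmga2, Arid3a, Mycn, Itgb3, Pf4, Flt3 and S100a8 were higher in every L28BME library than in any ME library, Ms4a3, Ctsg, Elane, Nkg7, H2-Aa, Ly6a and Myb were lower, and Mybbp1a overlapped.

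Among the 12 genes that rose most by the rule for named genes were Lin28b, Cstdc4, Cstdc5, Hmga2, Stfa1, Ighv1-82, Hnf4a, Ighv1-77, P2rx3, B4gat1 and Ccr7. Hmga2 (ENSMUSG00000056758, chromosome 10, 120361275 to 120476469 of GRCm38), a chromatin protein and let-7 target, rose from 7.32 ± 0.622 to 47.3 ± 2.68 TPM (log2 fold change 2.54, SE 0.078, limma adjusted p = 6.64e-05). Hnf4a, a nuclear receptor, rose from 0.475 ± 0.0929 to 6.45 ± 0.223 TPM, and Ccr7, a chemokine receptor, rose from 2.596 ± 0.374 to 12.5 ± 1.34 TPM. P2rx3, an ATP-gated ion channel, rose from 31.3 ± 0.902 to 138 ± 5.33 TPM (log2 fold change 2.11, SE 0.045, adjusted p = 1.88e-05). Its upstream end overlaps Ssrp1 on the opposite strand, and the sources used here do not say whether the authors' quantification used strand. Ighv1-82 and Ighv1-77, heavy chain variable segments, rose from 0.389 to 6.24 TPM and 2.91 to 18.01 TPM. Cstdc4, Cstdc5 and Stfa1, related stefin A genes on chromosome 16, rose from means under 1 TPM in ME to 7.19, 7.52 and 6.68 TPM. How reads were shared among these paralogs is uncertain. B4gat1, a glycosyltransferase, rose from 3.496 ± 0.754 to 16.2 ± 1.23 TPM. When the values of overlapping gene models were summed, its log2 fold change was 0.34 and did not pass (adjusted p = 0.148).

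Among the 12 genes that fell most were Msantd3, Spry1, H2-Eb1, Ly6a, Cited4, Lhfp, Itgam, H2-Aa, Cd300c, Cpne2 and Mt2. Msantd3 fell from 26.9 ± 1.38 to 4.78 ± 0.819 TPM (log2 fold change -2.28, SE 0.12, limma adjusted p = 3.20e-04), and the copine gene Cpne2 fell from 58.3 ± 3.06 to 18.5 ± 0.725 TPM. Ly6a, which encodes the sort marker Sca1, fell from 10.6 ± 1.09 to 2.07 ± 0.96998 TPM (log2 fold change -1.96, adjusted p = 0.00376). H2-Aa and H2-Eb1, chains of MHC class II, fell from 35.3 ± 0.738 to 10.2 ± 0.346 TPM and from 13.3 ± 1.15 to 2.58 ± 0.869 TPM. Mt2, a metallothionein, fell from 16.9 to 4.96 TPM. Cited4, a transcriptional coactivator, fell from 9.76 to 1.99 TPM, Lhfp from 8.25 to 1.85 TPM and Cd300c, an immune receptor, from 9.59 to 2.46 TPM. Spry1, an inhibitor of receptor tyrosine kinase signalling, fell from 7.59 ± 0.272 to 1.29 ± 1.14 TPM, with adjusted p = 0.0268. Its adjusted p was 0.0572 to 0.0799 without any 1 library other than L28BME replicate 2 or 3, and 0.115 with a pseudocount of 0.1. Itgam, which encodes CD11b, was called lower (41.2 ± 2.77 to 12.9 ± 5.83 TPM, adjusted p = 0.0208). Its adjusted p was 0.0576 to 0.0713 without any 1 library other than L28BME replicate 2 or 3. Summed with Gm49368, a gene model that overlaps it on chromosome 7, Itgam was at 41.4 ± 2.39 TPM in ME and 41.6 ± 6.05 TPM in L28BME. With all gene models that overlap at this locus summed, the value did not pass the test (limma adjusted p = 0.995).

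**Figure D2:**
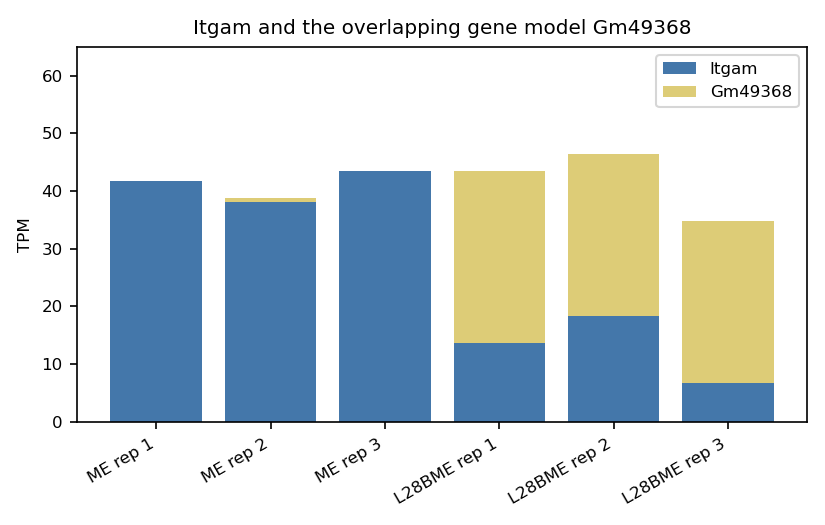
Itgam (blue) and the overlapping gene model Gm49368 (yellow) in each library, in TPM, stacked so that the full bar is their sum. Gm49368 rose from a mean of 0.231 TPM in ME to 28.7 TPM in L28BME while Itgam fell, and the summed means were 41.4 and 41.6 TPM.

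Targets of let-7, the microRNA family whose maturation LIN28B blocks, rose as a group. Of 32 tested members, 20 were higher and 2 lower in L28BME, and 24 and 2 were called when adjusted over the list alone. Besides Hmga2, the DNA-binding protein gene Arid3a rose from 27.5 ± 0.1799 to 85.97 ± 0.8604 TPM (log2 fold change 1.61, SE 0.035, limma adjusted p = 1.88e-05). Hif3a, a hypoxia-inducible factor subunit, rose from 0.127 ± 0.0754 to 4.81 ± 0.574 TPM. Mycn, a MYC family transcription factor, rose from 27.9 ± 1.43 to 52.9 ± 2.02 TPM, Igf2bp3, an RNA-binding protein of fetal tissue, from 15.6 ± 1.01 to 49.3 ± 8.44 TPM, and Arid3b from 7.703 to 25.6 TPM. The 2 members that fell were Rrm2, a ribonucleotide reductase subunit (352 to 292 TPM), and the cyclin-dependent kinase gene Cdk6 (129 to 106 TPM). Myc was at 289 ± 16.97 TPM in ME and 323 ± 34.04 TPM in L28BME and did not pass (adjusted p = 0.259). The list's median log2 fold change was 0.43, or 0.42 without Lin28b, and camera called it (adjusted p = 7.98e-12; adjusted p = 0.0326 with an estimated correlation). Without Lin28a and Lin28b, these were adjusted p = 1.79e-10 and adjusted p = 0.0434 with an estimated correlation.

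Genes of the fetal haematopoietic stem cell program were higher in 5 of 9 tested members, and none was lower, both over all genes and adjusted over the list alone. The list held 20 genes, and the rest, which include Igf2, H19 and Dlk1, were not among the tested genes. The 5 higher members were Lin28b, Hmga2, Arid3a, Igf2bp3 and Mycn, all of which are also on the let-7 list, so the counts are not independent. Tested members outside the let-7 list, Clec2d, Ezh2 and Cdkn1c, were not called (log2 fold change -0.23, 0.13 and 0.18). The list's median log2 fold change was 0.90, and 0.55 without Lin28b, which was listed at 0 in ME. Camera called the list (adjusted p = 2.99e-05), and the call was lost with an estimated correlation (adjusted p = 0.0807). Lin28b defines the contrast, and without it 8 members were tested (camera adjusted p = 6.77e-04; adjusted p = 0.150 with an estimated correlation). Without L28BME replicate 2, 1 member was also called lower. The adult stem and progenitor program was not called (camera adjusted p = 0.121), with 1 of 13 members higher and 5 lower, or 2 and 6 adjusted over the list alone. With a minimum of 5 TPM it was called as lower (adjusted p = 0.00707). Its lower members were the MHC class II genes H2-Aa, H2-Eb1, H2-Ab1 and Cd74, and Nfkbia, an inhibitor of NF-kB (39.5 to 34.2 TPM). Klf6, a zinc finger transcription factor, was the higher one (39.2 to 47.02 TPM). Some calls depended on single libraries. Adjusted p was 0.0631 to 0.118 without any 1 library other than L28BME replicate 2 for Cd74. It was 0.0909 to 0.132 without any 1 library other than ME replicate 2 for Nfkbia and 0.0515 to 0.0623 without any 1 library other than ME replicate 1 for Klf6. Lower members numbered 3 without ME replicate 1 or 3 or L28BME replicate 3.

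**Figure D3:**
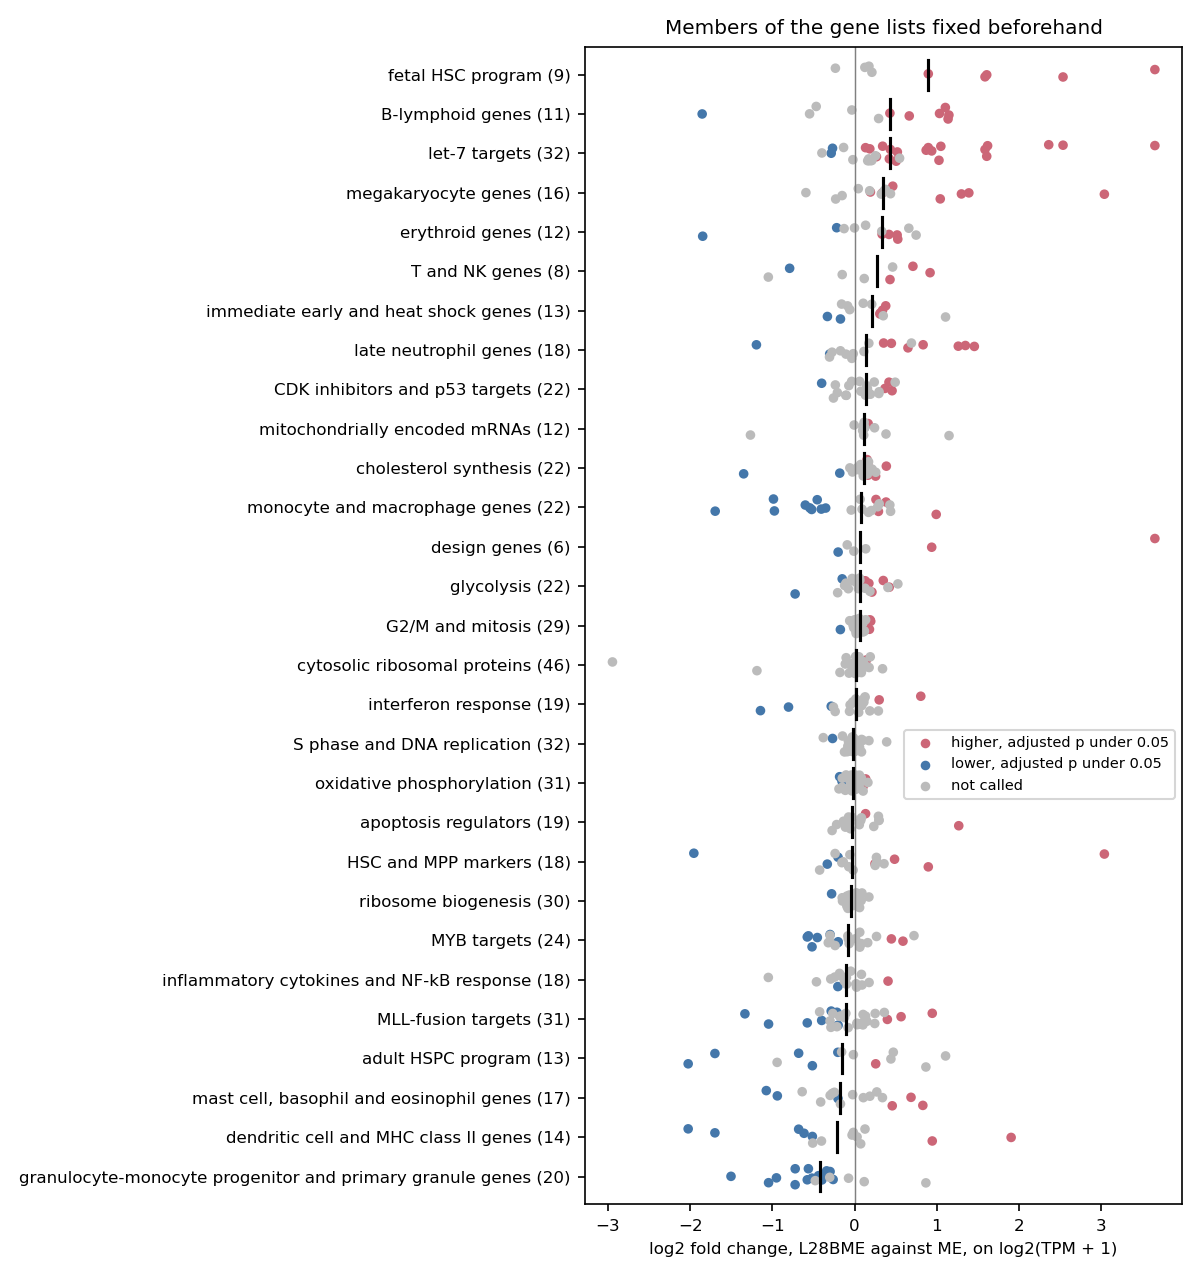
Log2 fold change of each tested member (points) of the 29 gene lists with at least 5 tested members, L28BME against ME on log2(TPM + 1), with members called higher in red, lower in blue and not called in grey. Black bars are list medians and numbers in parentheses are tested members; granulocyte-monocyte progenitor and primary granule genes had the lowest median (-0.42) and the fetal HSC program the highest (0.90).

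Genes of granulocyte-monocyte progenitors and primary granules fell as a group. Of 20 members, 15 were lower in L28BME and none was higher, or 16 lower when adjusted over the list alone. Ms4a3 (ENSMUSG00000024681, chromosome 19, 11629496 to 11640851 of GRCm38), a membrane protein gene of these progenitors, had a log2 fold change of -1.50 (SE 0.061, limma adjusted p = 1.57e-04). Ctsg had one of -0.56 (SE 0.023, adjusted p = 1.57e-04). Nkg7, a granule membrane protein gene, fell from 295 ± 19.1 to 142 ± 3.92 TPM, and Igsf6 from 59.5 ± 1.55 to 35.7 ± 0.672 TPM. Neutrophil elastase, Elane, fell from 1218 ± 26.96 to 851 ± 35.5 TPM, and Gfi1, a transcription factor of granulocyte development, from 63.7 ± 0.7602 to 42.4 ± 0.242 TPM. Myeloperoxidase, Mpo, fell from 5074 ± 19.3 to 4140.1 ± 368 TPM (adjusted p = 0.0277), and its call was lost at adjusted p = 0.0649 to 0.0887 without any 1 library other than L28BME replicate 3. Prtn3, Cebpa, Fcgr3, Csf2rb and Csf2ra did not pass. Cebpa was at 3.94 ± 0.521 TPM in ME and 9.34 ± 7.04 TPM in L28BME. The median log2 fold change was -0.42, and camera called the list (adjusted p = 1.03e-12; adjusted p = 0.0326 with an estimated correlation).

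Genes of later neutrophils moved both ways. S100a8 and S100a9, the calprotectin subunits, rose from 93.8 ± 1.71 to 241 ± 0.423 TPM and from 85.7 ± 4.89 to 237 ± 9.32 TPM. The granule protein genes Ngp and Ltf rose from 14.5 ± 0.578 to 36.2 ± 2.06 TPM and from 4.84 ± 0.1898 to 9.42 ± 0.306 TPM. Lyz2, lysozyme, fell from 171 ± 3.55 to 139 ± 4.899 TPM, and Cd177, a neutrophil surface protein, fell from 2.42 to 0.488 TPM, with adjusted p = 0.0534 without ME replicate 2. Of 18 members, 7 were higher and 2 lower (8 and 2 adjusted over the list alone), with 1 lower without ME replicate 2. The higher members numbered 5 without ME replicate 2 or 3 or L28BME replicate 3 and 6 without any 1 of the other libraries. Fcnb, a higher member, had limma adjusted p = 0.05999 to 0.0716 without any 1 library other than ME replicate 1. Mmp8, also higher, had 0.0503 to 0.107 without any 1 library other than L28BME replicate 2. Camera did not call the list (adjusted p = 0.0669). The list was called as higher with no filter on low values (adjusted p = 0.00708), with a minimum of 5 TPM (0.00636) and without ME replicate 2 (0.0468). Among 22 monocyte and macrophage genes, 9 were lower and 4 higher, or 9 and 5 adjusted over the list alone. The lower members included Itgam, whose call was lost with overlapping gene models summed (limma adjusted p = 0.995). They also included Cd14, with adjusted p = 0.0529 to 0.0653 without any 1 library other than L28BME replicate 3. Lower members numbered 7 without ME replicate 1, 2 or 3 or L28BME replicate 1, and 8 without L28BME replicate 2. Ly6c2, a marker of inflammatory monocytes, fell from 289 ± 12.2 to 190.4 ± 6.85 TPM. The chemokine genes Ccl9 and Ccl6 fell from 220.5 ± 5.27 to 151 ± 0.252 TPM and from 57.9 ± 1.799 to 40.1 ± 1.06 TPM. Ly86, which encodes MD-1, rose from 10.96 ± 0.04099 to 22.8 ± 0.459 TPM. Lgals3, Ctss and Csf1r also rose, the last with adjusted p = 0.0621 to 0.0925 without any 1 of the 6 libraries. With Itgam included, the median of the list was 0.08, its mean was -0.12 and its test pointed down, so the signs differ. It was not called (camera adjusted p = 0.344).

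Megakaryocyte genes were higher in 7 of 16 members and lower in none, or 9 and 0 adjusted over the list alone. The higher members numbered 6 without any 1 of the 6 libraries, and Itga2b lost its call each time (limma adjusted p = 0.0648 to 0.123). Pf4 had a log2 fold change of 1.39 (SE 0.10, limma adjusted p = 8.45e-04). Itgb3, the platelet integrin beta subunit, rose from 36.4 ± 1.23 to 50.6 ± 1.46 TPM, and Plek, pleckstrin, from 124 ± 1.25 to 157 ± 3.15 TPM. Camera called the list (adjusted p = 1.50e-04), and the call was lost with an estimated correlation (adjusted p = 0.185). Erythroid genes were higher in 4 and lower in 2 of 12 members (6 and 3 adjusted over the list alone). They were not called (camera adjusted p = 0.296). The higher members were Tfr2, transferrin receptor 2, which rose from 16.1 to 21.9 TPM, Gata1 (12.1 to 17.9 TPM), Gfi1b (41.4 to 52.6 TPM) and Aqp1 (1.29 to 2.27 TPM). The lower ones were Cited4 and Tfrc, the transferrin receptor (504 ± 1.62 to 433 ± 3.63 TPM). Adjusted p was 0.0673 without ME replicate 1, 0.0708 without ME replicate 2 and 0.0555 without L28BME replicate 1 for Gata1. It was 0.05599 to 0.0664 without any 1 library other than ME replicate 1 or L28BME replicate 2 for Gfi1b. It was 0.0521 to 0.0772 without any 1 of the 6 libraries for Aqp1. The higher members numbered 1 without ME replicate 2 or L28BME replicate 1 and 2 without ME replicate 1 or 3 or L28BME replicate 3. In the list of mast cell, basophil and eosinophil genes, 3 of 17 were higher and 3 lower (5 and 6 adjusted over the list alone). Camera did not call it (adjusted p = 0.555). Mcpt8, a basophil protease, fell from 125 ± 5.71 to 64.7 ± 2.44 TPM, and Gzmb, granzyme B, from 22.3 ± 2.08 to 10.03 ± 0.7199 TPM. Cpa3, a mast cell protease, fell from 239 to 208 TPM (adjusted p = 0.05797 without ME replicate 2 and 0.0525 without L28BME replicate 2). There were 5 lower members without ME replicate 1. The eosinophil genes Epx, Siglecf and Prg3 rose from 17.5 to 24.4 TPM, 7.199 to 12.2 TPM and 4.94 to 9.72 TPM. Prg3 had adjusted p = 0.0602 to 0.0741 without any 1 library other than L28BME replicate 1 or 2.

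B-lymphoid genes were higher in 6 and lower in 1 of 11 tested members, also when adjusted over the list alone. The higher members numbered 5 without L28BME replicate 1 or 2 and 4 without any 1 of the other libraries. Ebf1, a higher member, had limma adjusted p = 0.0538 to 0.0976 without any 1 of the 6 libraries. Il7r, also higher, had 0.0517 to 0.0729 without any 1 library other than L28BME replicate 1 or 2. Cd79b, a B cell receptor subunit, rose from 27.2 ± 0.673 to 56.9 ± 2.33 TPM, Ighm, the mu heavy chain gene, from 348 ± 3.82 to 469 ± 5.43 TPM, and Rag1, a subunit of the V(D)J recombinase, from 1.29 ± 0.0635 to 4.05 ± 0.0675 TPM. With overlapping gene models summed, the log2 fold change of Rag1 was 0.37 (adjusted p = 0.0285), against 1.14 for Rag1 alone. Dntt, terminal deoxynucleotidyl transferase, moved the other way, at 3.06, 2.42 and 2.41 TPM in ME and listed at 0 in every L28BME library (limma adjusted p = 6.81e-04). The list's median log2 fold change was 0.43, or 0.55 without Dntt, and camera called it (adjusted p = 0.0417), but not with an estimated correlation (adjusted p = 0.235). The call was also lost without ME replicate 1 (adjusted p = 0.0642), ME replicate 3 (0.0522), L28BME replicate 1 (0.0584) or L28BME replicate 3 (0.0777). With overlapping genes summed it was 0.110, and with protein-coding genes only it was 0.154. Of 8 T and NK genes, Lck, Cd7 and Notch1 rose from 19.8 to 33.1 TPM, 12.7 to 24.8 TPM and 18.3 to 25.1 TPM, and Thy1 fell from 144 ± 5.38 to 82.9 ± 7.56 TPM. Adjusted over the list alone, 4 were higher and 2 lower, and camera did not call the list (adjusted p = 0.296). Of 14 dendritic cell and MHC class II genes, Flt3 and Ccr7 rose, and H2-Aa, H2-Eb1, H2-Ab1 (36.9 to 22.5 TPM), Cd74 (70.4 to 49.3 TPM) and Itgax (4.64 to 2.68 TPM) fell. Adjusted over the list alone, 2 were higher and 6 lower. That list was not called (camera adjusted p = 0.189), and Itgax lost its call at adjusted p = 0.0561 to 0.0742 without any 1 library other than ME replicate 2. Cd74 lost its call at 0.0631 to 0.118 without any 1 library other than L28BME replicate 2. The lower members numbered 3 without ME replicate 1 or 3 or L28BME replicate 1 or 3. Only 3 stromal and endothelial genes were tested, too few for a list test. Sparc rose from 0.575 ± 0.163 to 3.11 ± 0.5299 TPM and Pdgfrb from 22.7 to 27.7 TPM (adjusted p = 0.0583 to 0.0668 without any 1 library other than ME replicate 1 or L28BME replicate 2). The higher members numbered 1 without ME replicate 2 or 3 or L28BME replicate 1 or 3. Acta2 was at 1.04 and 0.545 TPM and did not pass. The same 2 were called when adjusted over the list alone.

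Known targets of MLL fusions were mixed, with 3 of 31 higher and 7 lower, also when adjusted over the list alone. Flt3, a receptor tyrosine kinase of lymphoid-primed progenitors, rose from 96.6 ± 3.96 to 187 ± 2.099 TPM (log2 fold change 0.95, limma adjusted p = 1.60e-04), and Satb1, a chromatin organizer, from 31.97 ± 0.713 to 47.8 ± 1.57 TPM. Hoxa9 was at 101 ± 11.4 and 109 ± 11.6 TPM, and Meis1 at 40.6 ± 11.4 and 35.6 ± 4.799 TPM, neither of which passed. Camera did not call the list (adjusted p = 0.288). Of 24 targets of MYB, 7 were lower and 2 higher (9 and 3 adjusted over the list alone). The list was not called (camera adjusted p = 0.0669). Its lower members included Ctsg, Elane and Gfi1, which the primary granule list also holds, and the stem cell antigen gene Cd34 (506 ± 3.71 to 440.2 ± 3.76 TPM). Without the shared members, 19 were tested (camera adjusted p = 0.798). The higher members were Adora2b (4.63 to 7.46 TPM) and Cebpb (10.3 to 14.5 TPM), the latter with adjusted p = 0.0681 to 0.0867 without any 1 library other than L28BME replicate 2. The higher members numbered 1 without any 1 library other than L28BME replicate 2. Without ME replicate 2 the list was called (adjusted p = 0.0468). Stem cell and multipotent progenitor markers included 4 higher (among them Mycn, Mllt3 and Txnip) and 3 lower (Ly6a, Cd34 and Angpt1) of 18, or 6 and 4 adjusted over the list alone. The median of that list was -0.04 against a mean of 0.12 and a test that pointed up. It was not called (camera adjusted p = 0.624). Mllt3 had adjusted p = 0.0501 without ME replicate 3, and Txnip had 0.0501 to 0.0583 without any 1 library other than ME replicate 2 or L28BME replicate 1. There were 2 higher members without ME replicate 3.

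Few cell cycle and growth genes were called. Of 29 genes of G2/M and mitosis, Top2a, a DNA topoisomerase, rose from 535 ± 11.6 to 607 ± 6.81 TPM, Bub1b, a spindle checkpoint kinase, from 143 to 163 TPM, Aurka from 113 to 129 TPM and Nusap1 from 92.4 to 106 TPM. Cdc20, an anaphase activator, fell from 198 to 175 TPM. The same 4 and 1 were called adjusted over the list alone. Camera called the list (adjusted p = 0.0374), and the call was lost with an estimated correlation (adjusted p = 0.299). It was also lost without ME replicate 3 (0.0894), without L28BME replicate 1 (0.0695), with upper-quartile scaling (0.0604), without an intensity trend (0.0804) or with protein-coding genes only (0.0742). Adjusted p was 0.0504 to 0.0723 without any 1 library other than L28BME replicate 2 for Aurka. It was 0.0517 to 0.0743 without any 1 library other than L28BME replicate 3 for Nusap1 and 0.0504 without ME replicate 2 for Cdc20. Higher members numbered 2 without ME replicate 1, 2 or 3 or L28BME replicate 1. Lower members numbered 0 without ME replicate 2. Among 32 S phase genes only Rrm2 was called, as lower, also adjusted over the list alone. Mcm7, a replication helicase subunit, was at 424 ± 7.98 and 383 ± 20.999 TPM and did not pass (camera adjusted p = 0.471). The lower members numbered 2 without L28BME replicate 2 or 3. Of 22 CDK inhibitors and p53 targets, Sesn2 (22.03 to 30.6 TPM), Cdkn2d (32.8 to 42.7 TPM) and Btg2 (14.7 to 19.9 TPM) rose. Cdkn2c fell from 41.2 to 30.8 TPM, with adjusted p = 0.0759 to 0.107 without any 1 library other than ME replicate 2. The lower members numbered 0 without any 1 library other than ME replicate 2. Adjusted over the list alone, 4 were higher and 1 lower (camera adjusted p = 0.296). Of 30 ribosome biogenesis genes, Utp20 fell from 51.5 to 42.3 TPM (adjusted p = 0.0521 to 0.0702 without any 1 library other than L28BME replicate 1 or 2), also adjusted over the list alone. Camera did not call the list (adjusted p = 0.0669), but called it as lower with no filter on low values (adjusted p = 0.0347). Of 46 cytosolic ribosomal protein genes, Rps16 rose from 1538 to 1701 TPM (adjusted p = 0.0804 to 0.101 without any 1 library other than ME replicate 1). None was called adjusted over the list alone, and 1 was called lower without ME replicate 3. Their median was 0.02, their mean -0.06 and the test pointed up without a call (camera adjusted p = 0.469).

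Metabolic genes moved in both directions. Of 22 cholesterol synthesis genes, 5 rose and 2 fell, also adjusted over the list alone. Pmvk, a mevalonate pathway kinase, rose from 118 ± 2.86 to 155 ± 4.52 TPM and Msmo1 from 142 ± 7.07 to 170.3 ± 0.221 TPM, and Cyp51, Sqle and Lss also rose. Camera did not call the list (adjusted p = 0.0577), but called it as higher under several alternatives. These included no filter on low values (adjusted p = 0.00891), quantile normalization (0.0399), removal of mitochondrial and the 20 most abundant genes (0.0494) and leaving out ME replicate 3 (0.0245). Adjusted p was 0.0563 without ME replicate 3, 0.0566 without L28BME replicate 1 and 0.0518 without L28BME replicate 2 for Cyp51 and 0.0839 to 0.1099 without any 1 library other than ME replicate 1 for Sqle. It was 0.0684 to 0.121 without any 1 of the 6 libraries for Lss. The higher members numbered 2 without L28BME replicate 1 or 2 and 3 without ME replicate 2 or 3 or L28BME replicate 3, and the lower ones 1 without any 1 library other than ME replicate 3. Of 22 glycolysis genes, 6 were higher and 2 lower (7 and 2 adjusted over the list alone). Hk3, a hexokinase that the granule list also holds, fell from 211 ± 6.01 to 127 ± 10.02 TPM, and Hk1 from 164 to 148 TPM. Slc2a1, a glucose transporter, and Pgk1 rose from 36.6 to 46.9 TPM and 863 to 945 TPM. The higher members numbered 0 without ME replicate 3 or L28BME replicate 2, 1 without ME replicate 1 or 2 or L28BME replicate 1 and 2 without L28BME replicate 3, and Hk1 lost its call at adjusted p = 0.0576 to 0.0911 without any 1 of the 6 libraries. Camera did not call the list (adjusted p = 0.296). Slc2a1 had adjusted p = 0.0643 to 0.068995 without any 1 library other than ME replicate 1 or L28BME replicate 1. Pgk1 had 0.0607 to 0.0758 without any 1 library other than L28BME replicate 3. Of 31 oxidative phosphorylation genes, Uqcrfs1 and Sdhb rose and Cycs, cytochrome c, and Cox5a fell, also adjusted over the list alone, with log2 fold changes between -0.18 and 0.14 (camera adjusted p = 0.646). Adjusted p was 0.0835 to 0.112 without any 1 library other than L28BME replicate 2 for Uqcrfs1. It was 0.0951 to 0.122 without any 1 of the 6 libraries for Sdhb. It was 0.0748 to 0.0992 without any 1 library other than ME replicate 1 for Cycs and 0.08597 to 0.126 without any 1 library other than L28BME replicate 1 for Cox5a. Higher members numbered 0 without any 1 library other than L28BME replicate 2 and 1 without L28BME replicate 2. Lower members numbered 0 without ME replicate 2 or 3 or L28BME replicate 2 or 3 and 1 without ME replicate 1 or L28BME replicate 1. Of 12 mitochondrially encoded mRNAs, mt-Co1 rose from 12474 to 13994 TPM, also adjusted over the list alone, with adjusted p = 0.0693 to 0.0769 without any 1 library other than ME replicate 2 or L28BME replicate 3. Its adjusted p was 0.0536 with upper-quartile scaling, 0.0829 without an intensity trend and 0.213 with no filter on low values. Under quantile normalization this gene, the most abundant in every library, takes the same value in all 6 libraries (adjusted p = 1). That list was not called (camera adjusted p = 0.0669), but it was without L28BME replicate 3 (adjusted p = 0.0410).

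Signalling and stress genes moved in both directions, and camera called none of their 4 lists. Of 19 interferon response genes, Oas3 (0.774 to 2.11 TPM) and Gbp7 (20.97 to 26.03 TPM) rose and Cxcl10 (1.59 to 0.494 TPM), Xaf1 (2.797 to 0.714 TPM) and Ifit2 (10.1 to 8.14 TPM) fell, also adjusted over the list alone. The list had a median of 0.02, a mean of -0.04 and a test that pointed down without a call (camera adjusted p = 0.932). Adjusted p was 0.0625 to 0.0794 without any 1 library other than ME replicate 3 for Gbp7. It was 0.0634 to 0.0851 without any 1 library other than L28BME replicate 3 for Cxcl10. It was 0.0544 to 0.0755 without any 1 library other than ME replicate 3 for Xaf1 and 0.0701 to 0.1404 without any 1 of the 6 libraries for Ifit2. Higher members numbered 1 without any 1 library other than ME replicate 3. Lower members numbered 0 without ME replicate 1 or 2 or L28BME replicate 1 or 2 and 1 without ME replicate 3 or L28BME replicate 3. Of 18 inflammatory and NF-kB genes, Icam1, an adhesion receptor, rose from 21.4 ± 0.564 to 28.7 ± 0.859 TPM and Nfkbia fell (adjusted p = 0.0909 to 0.132 without any 1 library other than ME replicate 2). Adjusted over the list alone, 1 was higher and 0 were lower (camera adjusted p = 0.288). Of 19 apoptosis regulators, 2 were higher, also adjusted over the list alone, and numbered 1 without any 1 of the 6 libraries. The proapoptotic gene Bmf rose from 2.02 ± 0.133 to 6.29 ± 0.401 TPM (log2 fold change 1.27, limma adjusted p = 8.36e-04). Bcl2 was at 48.1 ± 0.617 TPM in ME and 50.1 ± 0.727 TPM in L28BME and did not pass (adjusted p = 0.3404). The list's median was -0.03, its mean 0.09 and its test pointed up without a call (camera adjusted p = 0.539). Of 13 immediate early and heat shock genes, which can follow handling, Zfp36 (28.5 to 37.4 TPM), Ier5, Fos and Ier2 rose and the chaperone genes Hspe1 (537 to 477 TPM) and Hsph1 (136 to 108 TPM) fell. Adjusted over the list alone, 4 were higher and 3 lower (camera adjusted p = 0.539). Adjusted p was 0.05297 to 0.07496 without any 1 library other than ME replicate 2 for Ier5 and 0.0748 to 0.0967 without any 1 of the 6 libraries for Fos. It was 0.0637 to 0.114 without any 1 library other than L28BME replicate 1 for Ier2. It was 0.0526 without ME replicate 2 for Hspe1 and 0.0516 to 0.0733 without any 1 library other than L28BME replicate 1 or 3 for Hsph1. Higher members numbered 1 without ME replicate 1 or 3 or L28BME replicate 2 or 3 and 2 without ME replicate 2 or L28BME replicate 1. Lower members numbered 0 without ME replicate 2 and 1 without ME replicate 1 or 3 or L28BME replicate 2.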

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

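Removal of a GC trend, summing of overlapping genes, restriction to protein-coding genes, lists without shared members and the fetal program without Lin28b were chosen after seeing the data; the other alternatives were planned. No called gene had the opposite call in any alternative fit, and the share of called genes that were higher lay between 50.7 and 58.0%, against 55.6%. Of the 1986 called genes, 158 shared exonic bases with another gene on the same strand. With overlapping genes summed, 111 of these 158 were called the same way and the rest were not, so dependence on read assignment is not limited to the genes named here. The median log2 fold change of all genes stayed within 0.011 of 0 under every scaling. Leaving out 1 library gave 617 to 693 genes higher and 461 to 582 lower, against 1105 and 881; fewer samples lower the number of calls by construction. A term for replicate number gave 548 higher and 400 lower and called 7 lists. Cholesterol synthesis (camera adjusted p = 0.0433) and mitochondrial mRNAs (0.0314) were gained and B-lymphoid genes (0.0889) lost. Correlations of residuals between libraries of equal number were -0.0743 to -0.0320, and the highest with another number were 0.0354 to 0.0551. These values gave no sign of pairing by number, but they cannot exclude a shared animal or day. At least 1 on the log2 scale gave 121 higher and 65 lower by construction, and an adjusted p of 0.10 gave 1605 and 1317. Camera with an estimated correlation called 2 lists and fry, which asks a different question, called 21, against 6; leaving out 1 library gave 4 to 8 lists.

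Of 2726 values of named genes under alternatives, 2527 kept their side of the threshold, 190 lost the call, 9 gained one and 0 reversed; 5 of those that kept their side were uncalled values that changed sign. Of 696 list results, 652 kept their side, 16 lost the call, 28 gained one and 0 reversed, with 11 uncalled sign changes. The let-7 and primary granule lists were called in every alternative. The fetal program without let-7 members had too few tested genes for a value. Count-based alternatives were not run, since no counts were used here, and unknown depth limits the reading of genes near 1 TPM.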

Other observations

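The tests of the summed Itgam values and of the share of granulocyte-monocyte cells were chosen after the results were seen, and the removal of a GC trend after the data were seen but before its own result; the summing of gene models at Neat1 was also chosen after seeing the data, and the other tests in this part were planned. With the libraries divided as labelled, 1986 genes and 6 lists were called, and the highest of the other splits gave 4 genes and 3 lists. For genes and for lists, 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

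Several genes outside the lists and the rule for named genes also rose, and were chosen after their values were seen. Tpm2, a tropomyosin, rose from 4.53 ± 0.401 to 19.3 ± 2.27 TPM, Ptafr, the receptor for platelet-activating factor, from 5.43 ± 0.205 to 15.1 ± 0.505 TPM, and P2rx1, an ATP-gated channel of platelets, from 23.3 ± 2.02 to 52.8 ± 0.894 TPM. They are listed among called genes with a let-7 site in the 3′ UTR, so their sites are not separate evidence. Other genes with a site fell, such as Sestd1 (14.1 ± 0.413 to 6.32 ± 1.08 TPM). Of all genes with the site, 20% were called higher and 5.75% lower. Gm27505, a gene model inside Neat1 on chromosome 19, rose from a mean of 0.586 to 89.4 TPM, while Neat1, a nuclear long noncoding RNA, rose from 10.1 to 21.2 TPM. Both values depend on how reads were assigned. With all gene models that overlap there summed, the log2 fold change was 3.21 (limma adjusted p = 1.62e-05), against 0.99 for Neat1 alone. Gm27505 spans only positions 5844638 to 5844747, and TPM are scaled by length. A few reads of so short a model can dominate the sum, which therefore does not measure the change of the locus. There were 36 genes with a mean of at least 20 TPM and a 4-fold range within a group, such as Rpl29, which was at 420, 422 and 25.7 TPM in ME and at 18.2, 22.7 and 21.9 TPM in L28BME, and limma called 0 of them.

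Genes with a let-7 site had higher values in L28BME, and release of let-7 targets may contribute. Among 10858 protein-coding genes with an annotated 3′ UTR, 400 held the 8-base site CTACCTCA, and their median log2 fold change exceeded that of the other 10458 by 0.10. Of 419 words of the same composition, 100% gave a smaller difference (at most 0.0683), and 20% of site genes were called higher against 9.20% of the others. Site genes have longer 3′ UTRs (medians of 2444 and 1113 bases), but against genes matched on length and expression the difference was 0.0897 (p = 0.0001, the smallest that 10000 permutations can give), which argues against length as the whole cause. Outside the fixed list, 386 site genes gave 0.0792 (permutation p = 0.0001, again the smallest possible); let-7 itself was not measured here, so this remains a hypothesis.

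The fall of primary granule genes was weighed against a GC trend and a changed share of cells. With a GC trend removed, 15 of the 20 members were still lower, which argues against such a trend as the whole cause. A lower share of granulocyte-monocyte cells beside unchanged other cells would raise the markers of every other type alike; a permutation test of whether 6 other cell type lists differed gave p = 0.0621 and missed the bound written for it, and only then was a count of lower members chosen in its place. By that count 12 of 78 members, from 5 lists, were lower and 25 higher, but some, such as Thy1 and MHC class II genes, may be expressed by the main cells, so the count is weak evidence. A change in cell composition and an effect of LIN28B on these genes both remain open.

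Itgam was called lower while Gm49368, which overlaps it on the same strand, was higher. The sum of both differed between groups by -0.000465 on the log2 scale (SE 0.132), which is consistent with reads of one locus being assigned to either model. A switch between transcripts of the locus would give the same sum and was not tested, so the fall of Itgam may not reflect less CD11b transcript.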
